A study of Mus musculus with 6 samples.

How the data were processed

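RNA from mouse liver was sequenced in 6 libraries, 3 labelled wild-type and 3 labelled Mdr2-knockout. Mdr2, whose gene symbol is Abcb4, is the hepatocyte transporter that moves phosphatidylcholine into bile, and mice that lack it are used as a model of chronic bile duct injury. The labels give the tissue and genotype, and say nothing of age, sex, strain, the allele or the part of the gene it removes. They do not say that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

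The authors deposited a table of whole-number read counts per gene symbol, with no normalization, and a table of FPKM values for the same genes and libraries. Per the submitters' processing notes, Trimmomatic, HISAT2, HTSeq, Cufflinks, DESeq, Bowtie2, StringTie and SAMtools were used with the mouse build mm10. The role of each tool, the versions, the annotation and the strand setting are not given in the sources used here. The deposited FPKM were proportional to the deposited counts within each gene and scaled by each library's total, so they carry the same reads under total-count scaling and are no independent measurement. Because the strand setting is not given, reads of overlapping or antisense genes cannot be told apart. Reads of close paralogs, such as the Cyp2c, Mup, Serpina1, Serpina3, Gsta, H2 and Hba families, could be split between copies or lost by the counting, and values of single members are uncertain.

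The columns of both tables carry the letters M and N with the numbers 1 to 3. M was read as Mdr2-knockout, since it begins that group's titles and no other title, and N as wild-type by elimination; the numbers were matched to the numbers in the titles. No value was used for this. No label spells out N, so each direction given here rests on that reading. The number of columns left without a sample was 0.

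Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), libraries were scaled by TMM factors, and a robust quasi-likelihood model with group as the only term was fitted to all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05 and, for a second count, a change of at least 2-fold. A positive log2 fold change means a higher level in the libraries labelled Mdr2-knockout. Standard errors (SE) were derived from the log2 fold change and its F statistic. CPM are counts divided by the TMM-scaled library size and multiplied by 1e6, given as mean ± SD over 3 libraries. Unless another tool is named, an adjusted p of a gene is from edgeR's quasi-likelihood test.

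Before the data were examined, 42 gene lists were fixed from general knowledge of mouse liver, bile duct injury and fibrosis, and 40 of them had at least 3 tested genes. Each was tested against the other tested genes with camera (limma 3.58.1) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. An estimated correlation and fry, which asks whether the genes of a list move on balance 1 way without setting them against other genes, were the alternatives. Members were also counted after Benjamini-Hochberg adjustment over the list alone. In each list for which no such count is printed, the counts adjusted over the list alone equalled those over all tested genes.

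Genes were named by a rule fixed before the data were examined: Abcb4; the 10 genes with the highest and the 10 with the lowest log2 fold change, and the 10 with the smallest p in each direction, among genes with an adjusted p under 0.05, a mean of at least 1 CPM over all 6 libraries and no overlap between the groups, leaving out predicted genes, pseudogenes and receptor segments; the 6 tested members of each list with the smallest p; and each measured member of the hedgehog list, of which 1 is not reported here. Any other gene is said to have been chosen after its values were seen. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group; where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Such intervals and bounds cover counting error only.

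The library totals ran from 17100393 to 18124467 counts. A floor of 3 counts in a single library equals 0.149 to 0.192 CPM. The pipeline was tested on simulated counts for the 12612 tested genes with 3 libraries against 3. It recovered 52.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 93.9% of those changed 4-fold, and 5.59% of its calls were false. Only 67, 67 and 66 genes were changed by these folds, with as many raised as lowered in all. The data here held far more changes, mostly upward at 2-fold, so that share of false calls need not carry over to them.

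The alternatives, fixed before the data were examined, were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at a mean of 1 CPM and the replicate number as a block. Further alternatives were the deposited FPKM on the log2(FPKM + 1) scale with limma-trend and a minimum mean of 0.5 (also with a pseudocount of 0.1, and without the minimum), an adjusted p under 0.01, a test against a 1.5-fold change, a prior count of 0.5 in place of 2 for the principal components, and each library left out in turn. The adjusted p under 0.01 and the test against a 1.5-fold change were applied to the counts of changed genes only, not to single genes or lists. Gene coordinates are from GENCODE M21 on GRCm38, the assembly named mm10 by UCSC; 16088 of the 16603 symbols matched a gene there. Figures were drawn with matplotlib 3.10.9. Isoforms, alleles and read-level checks were not analysed here, since the tables hold gene totals.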

Results

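Bulk RNA-seq of mouse liver was compared between 3 libraries labelled wild-type and 3 labelled Mdr2-knockout. The series title and design text place the comparison in a study of how hepatic progenitor cells expand and become bile duct cells, and of hedgehog signalling in liver fibrosis. Each library held 17100393 to 18124467 counts. Of the 16603 genes in the table, 326 had no count in any library and 12612 were tested. The table's columns carry letters, and the letter read as wild-type was assigned by elimination, so each direction rests on that reading. The labelled Mdr2-knockout libraries had counts for 15141 to 15152 genes, the labelled wild-type libraries for 14277 to 14359. Within a group, libraries correlated at r of at least 0.986 across genes, and between groups at no more than 0.959. The first principal component, which separated the groups, held 75.5% of the variance and the second 8.37%. Genes within a library are not independent replicates. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom of at least 14.03), which separate preparations of 1 sample could also do.

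Abcb4, the gene that encodes Mdr2, was higher in the libraries labelled Mdr2-knockout than in those labelled wild-type. Its level was 482 ± 42.4 CPM (SD, n = 3) against 324 ± 48.1 CPM (SD, n = 3), a log2 fold change of 0.57 (SE 0.12, edgeR adjusted p = 0.00389), and each of the 3 labelled knockout libraries lay above each labelled wild-type library. It passed with each other scaling, test against no change, filter and set of 5 libraries tried. The raw counts were 10071, 10188 and 8347 in labelled Mdr2-knockout replicates 1, 2 and 3, and 5190, 5776 and 4330 in labelled wild-type replicates 1, 2 and 3. The paralogs Abcb1a and Abcb1b, which export drugs and other compounds and of which Abcb1b stands outside the naming rule, were far lower, at no more than 7.17 CPM in any library. Both were higher in the labelled Mdr2-knockout libraries. Abcb1a rose from 1.74 ± 0.441 to 5.81 ± 1.18 CPM (log2 fold change 1.74, edgeR adjusted p = 0.000497). Abcb1b lay at 1.208 to 3.155 CPM in the labelled wild-type and 5.404 to 6.798 CPM in the labelled Mdr2-knockout libraries. Abcb4 lies on chromosome 5 from 8893717 to 8959231 (GRCm38), and the count covers the whole gene. The labels do not say which part the allele removes, so reads from outside that part may be counted and the count cannot check the genotype. Because this gene goes against its label, groups are named by their labels throughout, and each direction below is that of the labelled libraries.

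**Figure D1:**
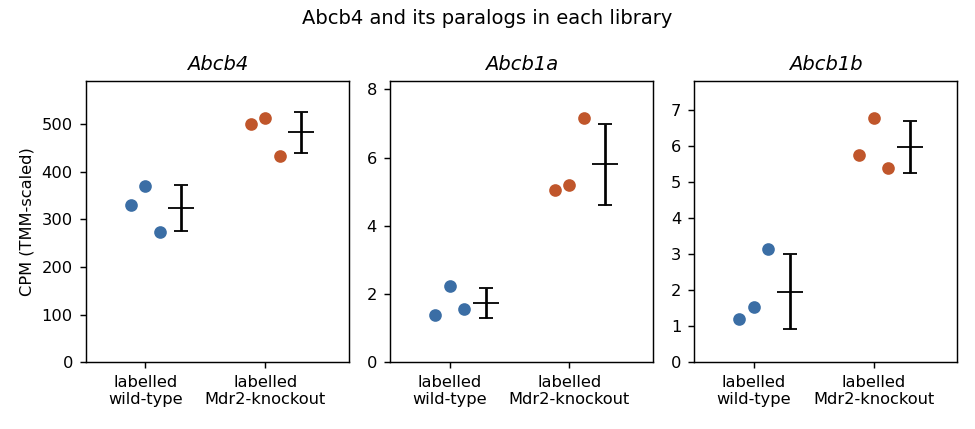
CPM (TMM-scaled, linear axes from 0) of Abcb4 and its paralogs Abcb1a and Abcb1b in each library; points are the 3 libraries of each labelled group, and the black marks beside them are the mean ± SD. Abcb4 lies between 434 and 513 CPM in the labelled Mdr2-knockout libraries and between 273 and 369 CPM in the labelled wild-type libraries, while the paralogs stay at or under 7.17 CPM.

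Gene expression differed widely between the labelled groups, and large changes were mostly increases. Anxa5, a phospholipid-binding annexin, rose from 50.3 ± 3.84 CPM in the labelled wild-type to 264 ± 5.75 CPM in the labelled Mdr2-knockout libraries (log2 fold change 2.39, SE 0.08, adjusted p = 3.08e-07, n = 3 per group, edgeR). Mfge8 rose from 9.4 ± 1.12 to 61.1 ± 5.52 CPM, Cd24a from 1.52 ± 0.27 to 23.6 ± 2.45 CPM and Cd63 from 2.29 ± 0.277 to 19.1 ± 2.09 CPM. Among the lower genes, Serpina6, which encodes the corticosteroid carrier of plasma, went from 104 ± 4.65 to 42.2 ± 1.22 CPM, and the sodium-dicarboxylate transporter Slc13a2 from 8.94 ± 0.718 to 0.388 ± 0.174 CPM. The cytochrome P450 genes Cyp2c37, Cyp2c29 and Cyp2c40 had log2 fold changes of -2.41, -1.98 and -4.20, and the major urinary protein genes Mup1 and Mup3 of -3.05 and -1.71.

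Of the 12612 tested genes, 4685 changed at an edgeR adjusted p under 0.05, 2634 of them higher and 2051 lower in the labelled Mdr2-knockout libraries. At least 2-fold changes numbered 1499, of which 1404 were higher and 95 lower. The groups did not overlap for 6471 tested genes, 51.3% against the 10% that chance gives for 3 against 3, and for 4629 of the 4685 called genes. The split of directions depended on the scaling: 56.2% of calls were higher with TMM, 67.2% with upper-quartile scaling (2938 higher, 1433 lower) and 94.7% with total counts (5943 higher, 330 lower). With RLE factors it was 54.1%. Total-count scaling shifted the median log2 fold change of all tested genes by 0.29 against TMM, and the changes below are relative to the TMM reference. Of the 2-fold changes, 93.3% to 97.6% were higher under the 4 scalings.

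Several of the steepest changes were in genes that the labelled wild-type libraries hardly held. Gabrp, a GABA receptor subunit gene, had 0 counts in the labelled wild-type group and 234 in the labelled Mdr2-knockout group, at least 62.2-fold higher against a floor of 3 counts over the group. Sprr1a and the neutrophil chemokine gene Cxcl5 also had 0 counts in the former and were at least 35.1-fold and 34.8-fold higher. Cftr, the chloride channel of bile duct epithelium, had 1 count against 224, a ratio of 179 with a 95% counting interval of 31.7 to 7080, and the fibrillin gene Fbn2 1 count against 330, a ratio of 263 (46.9 to 10400). Lrtm2, Insyn1 and Sdr16c5 had 2, 1 and 1 counts, with ratios of 139 (38.1 to 1150), 159 (28.1 to 6300) and 140 (24.9 to 5570). The neurotrophin receptor gene Ntrk2 rose from 0.381 ± 0.254 to 76.9 ± 23.9 CPM and Dmbt1, a mucin-like scavenger receptor gene, from 0.17 ± 0.295 to 28.1 ± 5.91 CPM. In the other direction, Cyp2c69 had 133 counts in the labelled wild-type and 2 in the labelled Mdr2-knockout libraries, a ratio of 83.4 (22.6 to 696).

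For hedgehog signalling, which the series title names, 4 of the 14 tested members were higher in the labelled Mdr2-knockout libraries, 0 were lower and 10 did not pass. With total-count scaling 8 were higher and 0 lower, and with RLE factors 4 were higher and 1 lower. The 4 with TMM were the ligand gene Ihh (log2 fold change 1.38, SE 0.45, adjusted p = 0.0472), the co-receptor genes Cdon (1.03, SE 0.27, adjusted p = 0.0135) and Boc (1.26, SE 0.40, adjusted p = 0.0294), and the signal transducer gene Smo (0.66, SE 0.16, adjusted p = 0.00943), all by edgeR. Ihh stood at 1.93 ± 0.591 and 5.03 ± 2.68 CPM (n = 3 per labelled group). Of the genes known as targets of the pathway, Ptch1 had a log2 fold change of -0.14 (SE 0.09, edgeR adjusted p = 0.254) and Hhip of -0.80 (SE 0.29, edgeR adjusted p = 0.0538). Gli1, a further target, had 2 counts over the labelled wild-type and 37 over the labelled Mdr2-knockout libraries, with no overlap between the groups. Its ratio was 14.7 with a 95% counting interval of 3.8 to 126. The low-count filter left Gli1 out of the main test, and its values in fits without that filter are not given here. Shh, Dhh, Gli2, Kif7 and Scube2 were also left out by that filter. Shh had 4 and 3 counts and Gli2 had 8 and 12. Gli3 (1.27, adjusted p = 0.0547), Hhat (0.79), Stk36 (0.57), Gas1 (-0.33), Spop (-0.08), Disp1 (-0.06) and Sufu (-0.04) did not pass.

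As a list, the hedgehog genes did not stand apart from the other tested genes (camera adjusted p = 0.724; adjusted p = 0.835 with an estimated correlation), while fry, which makes no comparison with other genes, gave an adjusted p of 0.0391. Adjusted over the list alone, 5 members were higher and 2 lower. The call of Smo held with each other scaling, test against no change, filter and set of 5 libraries tried, and those of Ihh, Cdon and Boc did not. The gene Ihh gave an edgeR adjusted p of 0.0693, 0.148 and 0.15 without labelled wild-type replicate 1, 2 or 3, and of 0.102 and 0.0931 without labelled Mdr2-knockout replicate 1 or 2. With limma-voom it was 0.0843 and without the low-count filter 0.0711. The gene Boc gave 0.0908 and 0.0568 without labelled wild-type replicate 1 or 3, and 0.067, 0.0769 and 0.0588 without labelled Mdr2-knockout replicate 1, 2 or 3, and 0.0512 with DESeq2. The gene Cdon gave 0.058 without labelled wild-type replicate 2 and 0.0602 without labelled Mdr2-knockout replicate 2.

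**Figure D2:**
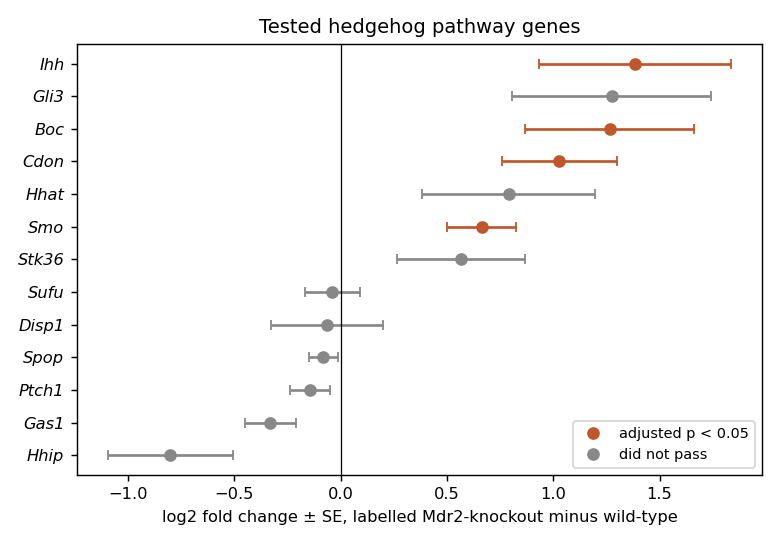
Log2 fold change (horizontal axis, labelled Mdr2-knockout minus labelled wild-type) with its SE for tested hedgehog pathway genes; orange points passed an edgeR adjusted p of 0.05 and grey points did not. Ihh, Boc, Cdon and Smo lie at 1.38, 1.26, 1.03 and 0.66, and Hhip at -0.80; Spop, at -0.08, turns to 0.21 with total-count scaling.

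Bile duct cell markers rose together in the labelled Mdr2-knockout libraries. Of 23 tested cholangiocyte markers, 22 were higher, 0 were lower and 1 did not pass (camera adjusted p = 1.17e-42; adjusted p = 0.0278 with an estimated correlation). The epithelial adhesion gene Epcam rose from 1.12 ± 0.189 to 12 ± 0.64 CPM (log2 fold change 3.41, SE 0.17, edgeR adjusted p = 1.8e-06, n = 3 per group), the keratin gene Krt19 from 0.91 ± 0.204 to 10.6 ± 0.748 CPM (3.53, SE 0.20) and the tight junction gene Cldn4 from 0.085 ± 0.0736 to 4.98 ± 0.269 CPM. Bicc1 and the transcription factor gene Ehf had log2 fold changes of 2.58 and 3.67.

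Hepatic progenitor markers were higher for 11 of 15 tested members, 0 were lower and 4 did not pass (camera adjusted p = 1.28e-12; adjusted p = 0.0278 with an estimated correlation). Besides Cd24a, they included the transcription factor genes Sox4, which rose from 1.33 ± 0.385 to 10.8 ± 1.36 CPM, and Sox9, from 8.8 ± 1.25 to 15.6 ± 1.6 CPM (log2 fold change 0.82, SE 0.13, edgeR adjusted p = 0.00116), and Prom1, from 1.12 ± 0.356 to 6.88 ± 2.06 CPM. This list shares genes with the other marker lists: 9 of its 22 genes, Epcam, Krt19 and Sox9 among them, stand in another list, as do 6 of the 25 cholangiocyte markers, so the lists are not independent. Fetal liver and liver tumour genes were higher for 9 of 12 tested members and lower for 0 (10 and 0 adjusted over the list alone; camera adjusted p = 9.17e-13; adjusted p = 0.0278 with an estimated correlation), with log2 fold changes of 4.21 for Ly6d, 4.56 for Tspan8 and 1.81 for Golm1. This result rests partly on shared genes, since 5 of this list's genes stand in another list, Tspan8 among the cholangiocyte markers and Cd24a among the progenitor markers.

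Matrix genes rose broadly. Of 30 tested genes of fibrillar collagen and matrix, 27 were higher, 1 was lower and 2 did not pass in the labelled Mdr2-knockout libraries (28 and 1 adjusted over the list alone). Elastin (Eln) rose from 3.47 ± 0.024 to 19.1 ± 1.2 CPM (log2 fold change 2.46, SE 0.12, edgeR adjusted p = 1.47e-06, n = 3 per group), Col5a2 from 2.26 ± 0.453 to 15.8 ± 1.35 CPM and lumican (Lum) from 6.49 ± 1.43 to 33.2 ± 3.11 CPM. Col1a1 (3.03) and Col3a1 (2.77), and the lower member Fn1 (-0.67), were chosen after their values were seen; Fn1 encodes fibronectin, which hepatocytes also secrete into plasma. The list's camera adjusted p was 5.28e-27, and the call was lost with an estimated correlation (adjusted p = 0.0949).

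Matrix remodelling enzymes and their inhibitors were higher for 20 and lower for 1 of 25 tested members (22 and 1 adjusted over the list alone; camera adjusted p = 6.77e-19; adjusted p = 0.0422 with an estimated correlation). The gelatinase gene Mmp2 rose from 4.21 ± 0.507 to 23.5 ± 4.02 CPM, the macrophage elastase gene Mmp12 from 0.699 ± 0.505 to 16.3 ± 2.33 CPM and the inhibitor gene Timp2 from 12.7 ± 1.78 to 40.8 ± 4.35 CPM. TGF-beta and profibrotic signalling genes were higher for 16 and lower for 1 of 23 (17 and 1 adjusted over the list alone; camera adjusted p = 1.3e-08; adjusted p = 0.0309 with an estimated correlation); Ltbp2, Tgfbr2 and Tgfb3 had log2 fold changes of 3.36, 1.41 and 2.73. Stellate cell and fibroblast markers were higher for 13 of 22 and lower for 0, with the receptor gene Pdgfrb at 1.53 and the fibulin gene Fbln1 at 3.01 (camera adjusted p = 1.3e-08; adjusted p = 0.242 with an estimated correlation). Acta2, the smooth muscle actin gene used as a mark of activated stellate cells and chosen after its value was seen, had a log2 fold change of 0.31 and did not pass (edgeR adjusted p = 0.7).

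Markers of monocytes, macrophages and dendritic cells, and chemokine genes, were mostly higher in the labelled Mdr2-knockout libraries. Of 24 tested monocyte and macrophage markers, 21 were higher and 0 lower: Gpnmb rose from 0.445 ± 0.0662 to 10.4 ± 2.42 CPM (log2 fold change 4.52, SE 0.27, edgeR adjusted p = 3.03e-06, n = 3 per group) and the chemokine receptor gene Ccr2 from 0.888 ± 0.324 to 6.86 ± 1.31 CPM. The list had a camera adjusted p of 2.54e-17, which was lost with an estimated correlation (adjusted p = 0.162). Dendritic cell markers were higher for 10 of 12 and lower for 0, with the class II genes H2-Eb1 and Cd74 at 1.99 and 1.74 (camera adjusted p = 3.76e-11; adjusted p = 0.0949 with an estimated correlation). Chemokines and cytokines were higher for 12 of 18 and lower for 0 (13 and 0 adjusted over the list alone), with Spp1, the osteopontin gene, rising from 36.1 ± 8.69 to 293 ± 19.2 CPM and Ccl2 from 0.255 ± 0.17 to 3.87 ± 0.404 CPM (camera adjusted p = 2.6e-10; adjusted p = 0.0915 with an estimated correlation).

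The lists of other blood and vessel cell markers did not pass the camera test. Of 12 tested Kupffer cell markers, 2 were higher and 1 lower (camera adjusted p = 0.639); with total-count scaling 5 were higher and 0 lower. The lower 1, Nr1h3 (-0.25, edgeR adjusted p = 0.0245), turned positive with total-count scaling and did not pass there, nor with several other alternatives. Neutrophil markers were higher for 3 and lower for 1 of 7 (camera adjusted p = 0.241, and 0.0108 without labelled wild-type replicate 3), with Cxcr2 at 2.79 and Csf3r at 1.31. With total counts 5 were higher and 1 lower. The lower neutrophil marker with TMM was Wfdc21 (log2 fold change -0.67), at 251 ± 34.6 and 157 ± 27.4 CPM. Those levels lay far above the 2.58 ± 1.08 and 6.41 ± 1.04 CPM of Csf3r. Of 6 tested T and NK cell markers, Il7r was higher (1.83) and Zap70 lower (-1.86), and the list test (camera adjusted p = 0.792, downward) had the opposite sign to its median of 0.55 and mean of 0.27. B and plasma cell markers were higher for 1 of 6, the joining chain gene Jchain (2.51), and lower for 0 (camera adjusted p = 0.488). With upper-quartile scaling 2 of these were higher, and with total counts 3 were, while 2 T and NK cell markers were higher and 1 lower with total counts. Endothelial markers were higher for 4 and lower for 6 of 21, with Cd34 and Cd36 at 2.43 and 1.62 and Oit3 at -0.54; the list test was downward (camera adjusted p = 0.725) while the median was 0.03 and the mean 0.13. Under total-count scaling 11 endothelial markers were higher and 1 lower.

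Genes typical of hepatocytes were lower relative to the TMM reference. Of 26 tested hepatocyte genes, 20 were lower and 0 higher in the labelled Mdr2-knockout libraries (21 and 0 adjusted over the list alone). Albumin (Alb) went from 85388 ± 4348 to 49467 ± 848 CPM (log2 fold change -0.79, SE 0.08, edgeR adjusted p = 5.46e-05, n = 3 per group), transthyretin (Ttr) from 4968 ± 227 to 2788 ± 176 CPM and Apoa2 from 3930 ± 318 to 2361 ± 139 CPM. As a share of all counts, Alb took 7.31% to 7.99% in the labelled wild-type and 5.41% to 5.53% in the labelled Mdr2-knockout libraries. The list's camera adjusted p was 5.57e-07, a call lost with an estimated correlation (adjusted p = 0.0763). With total-count scaling 9 members were lower and 2 higher.

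Detoxifying enzymes changed in both directions. In the xenobiotic metabolism list, 13 of 22 tested members were lower and 3 higher (15 and 3 adjusted over the list alone; camera adjusted p = 9.52e-08; adjusted p = 0.0384 with an estimated correlation); Cyp2e1 went from 9495 ± 610 to 3250 ± 607 CPM while Cyp3a11 rose from 2338 ± 331 to 5627 ± 895 CPM. Antioxidant response genes were higher for 11 and lower for 0 of 22 (12 and 1 adjusted over the list alone), among them Srxn1 (0.85), Gsta4 (1.18) and the cystine carrier gene Slc7a11, with 0 counts against 58, at least 15.4-fold higher (camera adjusted p = 0.00201; adjusted p = 0.405 with an estimated correlation).

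Relative to the TMM reference, some bile acid synthesis genes were lower and transport genes were mixed. Bile acid synthesis and conjugation genes were lower for 9 of 17 and higher for 0, with Slc27a2 at -1.01, Slc27a5 at -0.72 and the hydroxylase gene Cyp7b1 at -0.89 (camera adjusted p = 0.00135; adjusted p = 0.346 with an estimated correlation). With upper-quartile scaling 7 were lower and 0 higher, and with total counts 4 were lower and 1 higher, with a median of -0.06. Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis and was chosen after its value was seen, had a log2 fold change of 1.55 and did not pass (edgeR adjusted p = 0.081). Of 21 tested bile acid and phospholipid transport genes, 7 were higher and 7 lower (camera adjusted p = 0.639, downward, with a median of -0.08 and a mean of 0.06): the uptake carrier gene Slc10a1 went from 601 ± 69.3 to 334 ± 33.1 CPM, while Slco1a4 rose from 33.9 ± 2.39 to 69.7 ± 4.49 CPM and the export pump gene Abcc1 had a log2 fold change of 1.37. With total counts 9 transport genes were higher and 5 lower.

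Lipid and plasma protein genes gave weaker patterns. Fatty acid oxidation genes and PPARA targets were lower for 8 and higher for 1 of 24, with Cpt2 at -0.79 and Pdk4 at 1.30 (camera adjusted p = 0.00679; adjusted p = 0.774 with an estimated correlation and 0.232 with fry). With upper-quartile scaling 5 were lower and 1 higher, and with total counts 1 was lower and 1 higher. Fatty acid synthesis genes were higher for 4 and lower for 5 of 19 (4 and 6 adjusted over the list alone; camera adjusted p = 0.724, downward, with a median of -0.06 and a mean of 0.08), with Acaca at 0.73 and Mlxipl at -0.66. With total counts 5 of these were higher and 2 lower. Cholesterol synthesis and uptake genes were higher for 4 and lower for 2 of 25 (camera adjusted p = 0.639), with Sqle at 1.29 and Tm7sf2 at -0.90. With total counts 11 of these were higher and 2 lower. Acute phase protein genes were lower for 6 and higher for 1 of 24, with Crp at -0.61 and Il1rn at 2.56. Their camera adjusted p of 0.03 was lost with an estimated correlation (adjusted p = 0.774), with fry (0.341), with the replicate block (0.056), and without labelled wild-type replicate 3 (0.411) or labelled Mdr2-knockout replicate 1 or 3 (0.0765 and 0.0942).

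Among other signalling and growth lists, cell division genes were higher for 9 of 20 and lower for 0 in the labelled Mdr2-knockout libraries (10 and 0 adjusted over the list alone). Cyclin D1 (Ccnd1) rose from 5.16 ± 0.996 to 25.2 ± 1.36 CPM (log2 fold change 2.29, SE 0.13, edgeR adjusted p = 2.66e-06, n = 3 per group) and the proliferation marker gene Mki67 had a log2 fold change of 1.83. The camera adjusted p was 0.00378 (adjusted p = 0.446 with an estimated correlation, and 0.0796 for the cell division genes list with total-count scaling). The list of YAP target genes also holds components of the pathway, such as Tead1, so it does not measure target genes alone. Its members were higher for 9 and lower for 4 of 19 (10 and 4 adjusted over the list alone). Ajuba and Tead1 stood at 1.51 and 0.98 and Wwc1 at -0.78. Ankrd1 had 1 count against 143, a ratio of 114 (20.1 to 4530). The YAP list had a camera adjusted p of 0.0245, and of 0.346 with an estimated correlation. Notch pathway genes were higher for 3 of 15 and lower for 0 (2 and 0 adjusted over the list alone), with the ligand gene Jag1 at 0.99 and Heyl at 1.28 (camera adjusted p = 0.488, fry adjusted p = 0.0376). Wnt and pericentral genes were lower for 4 of 20 and higher for 0, with Notum at -0.70 beside Cyp2e1. Their median of -0.07 turned to 0.23 with total-count scaling, with 4 higher and 2 lower. With that scaling the members higher and lower were 14 and 0 for cell division, 13 and 1 for YAP targets and 8 and 0 for Notch. The camera adjusted p of 0.0317 became an adjusted p of 0.398 with an estimated correlation, 0.0735 with limma-voom and 0.066 without labelled Mdr2-knockout replicate 2.

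The lists of p53 and senescence, endoplasmic reticulum stress, interferon response, and immediate early and heat shock genes did not pass the camera test. For p53 and senescence genes, 2 were higher and 1 lower of 16 (2 and 0 adjusted over the list alone; camera adjusted p = 0.724), with Phlda3 and Eda2r at 1.65 and 1.57. For endoplasmic reticulum stress genes, 1 was higher and 1 lower of 18 (1 and 0 adjusted over the list alone; camera adjusted p = 0.506, downward, with a median of -0.03 and a mean of 0.01), the higher being Atf3 (2.19). Interferon response genes were higher for 4 and lower for 1 of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.504), with Ifi44 at 1.06 and Iigp1 at -0.62. Immediate early and heat shock genes were higher for 5 and lower for 2 of 19 (camera adjusted p = 0.488), with Klf6 at 1.90 and Ier3 at 2.52. With total-count scaling the members higher and lower were 9 and 0 for p53 and senescence, 5 and 0 for endoplasmic reticulum stress, 10 and 1 for interferon response, and 7 and 0 for immediate early and heat shock genes.

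Lists that can mark sex, time of day or other tissue in a sample were measured in the same way. Clock genes were lower for 6 of 18 and higher for 0 in the labelled Mdr2-knockout libraries, with Nfil3 at -0.85 and Ciart at -1.57 (camera adjusted p = 0.00888; adjusted p = 0.122 with an estimated correlation). With total counts 3 were lower and 1 higher. The clock list also passed with fry (adjusted p = 0.000906). A difference in the time of collection between the groups was not tested and stays open. Male-biased liver genes were lower for 10 and higher for 2 of 18 (10 and 3 adjusted over the list alone), with Slco1a1 at -1.31, Serpina1e at -1.20 and Mup20 at 1.53 (camera adjusted p = 0.000989; adjusted p = 0.0883 with an estimated correlation). With total counts 8 of these were lower and 5 higher. Female-biased liver genes were higher for 3 of 7 and lower for 0; besides Fmo2 (1.05) these were Prom1 and Ntrk2 (camera adjusted p = 0.00785; adjusted p = 0.162 with an estimated correlation, 0.172 with DESeq2 and 0.315 with limma-voom). The female-biased liver genes list also lost its call with total-count scaling (0.0591) and without the low-count filter (0.211). The call of the gene Fmo2 was lost without labelled wild-type replicate 1, 2 or 3 (edgeR adjusted p of 0.108, 0.0937 and 0.122) or labelled Mdr2-knockout replicate 2 (0.0589), without the low-count filter (0.082) and with the replicate block (0.156). Of 4 tested sex chromosome genes, all of them Y-linked and read in all 6 libraries, Eif2s3y was higher (0.30) and the other 3 did not pass (camera adjusted p = 0.653). With total counts 4 of 4 were higher. Ddx3y, Eif2s3y, Uty and Kdm5d stood at 68.7, 40.3, 17.7 and 19.1 CPM in the labelled wild-type libraries. In the labelled Mdr2-knockout libraries they stood at 70.5, 49.5, 20.6 and 20.1 CPM. Such similar levels argue against a difference of sex between the groups as the cause of the changes in the sex-biased lists.

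Mesothelial markers were higher for 4 of 4, the keratin genes Krt8 and Krt18 (1.18 and 0.99), which hepatocytes and bile duct cells also express, Msln (2.82) and Gpm6a (1.05) (camera adjusted p = 0.00679; adjusted p = 0.122 with an estimated correlation). The call of the gene Gpm6a was lost without labelled wild-type replicate 1 or 3 (edgeR adjusted p of 0.0609 and 0.0522) or labelled Mdr2-knockout replicate 3 (0.0771). Gallbladder, pancreas and gut epithelium markers were higher for 2 of 6, Dmbt1 and Vil1 (3.57), and lower for 1, Cela1 (-1.66); the camera test was upward (adjusted p = 0.348), with a mean of 1.37 and a median of -0.22, and fry gave an adjusted p of 0.0139. Red cell and platelet genes were lower for 2 of 7 and higher for 0 (1 and 0 adjusted over the list alone; camera adjusted p = 0.348), and with total counts 0 were lower. Of 2 tested adipocyte and muscle genes, Plin4 was higher (1.09) and Mylpf did not pass (-0.22). The call of the gene Plin4 was lost without labelled wild-type replicate 1 or 3 (edgeR adjusted p of 0.0998 and 0.101) or labelled Mdr2-knockout replicate 2 (0.052), and without the low-count filter (0.0581). The list was too small to test. Mitochondrially encoded genes were not analysed here. In all, 23 of the 40 tested lists had a camera adjusted p under 0.05, and 6 of these also with an estimated correlation.

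**Figure D3:**
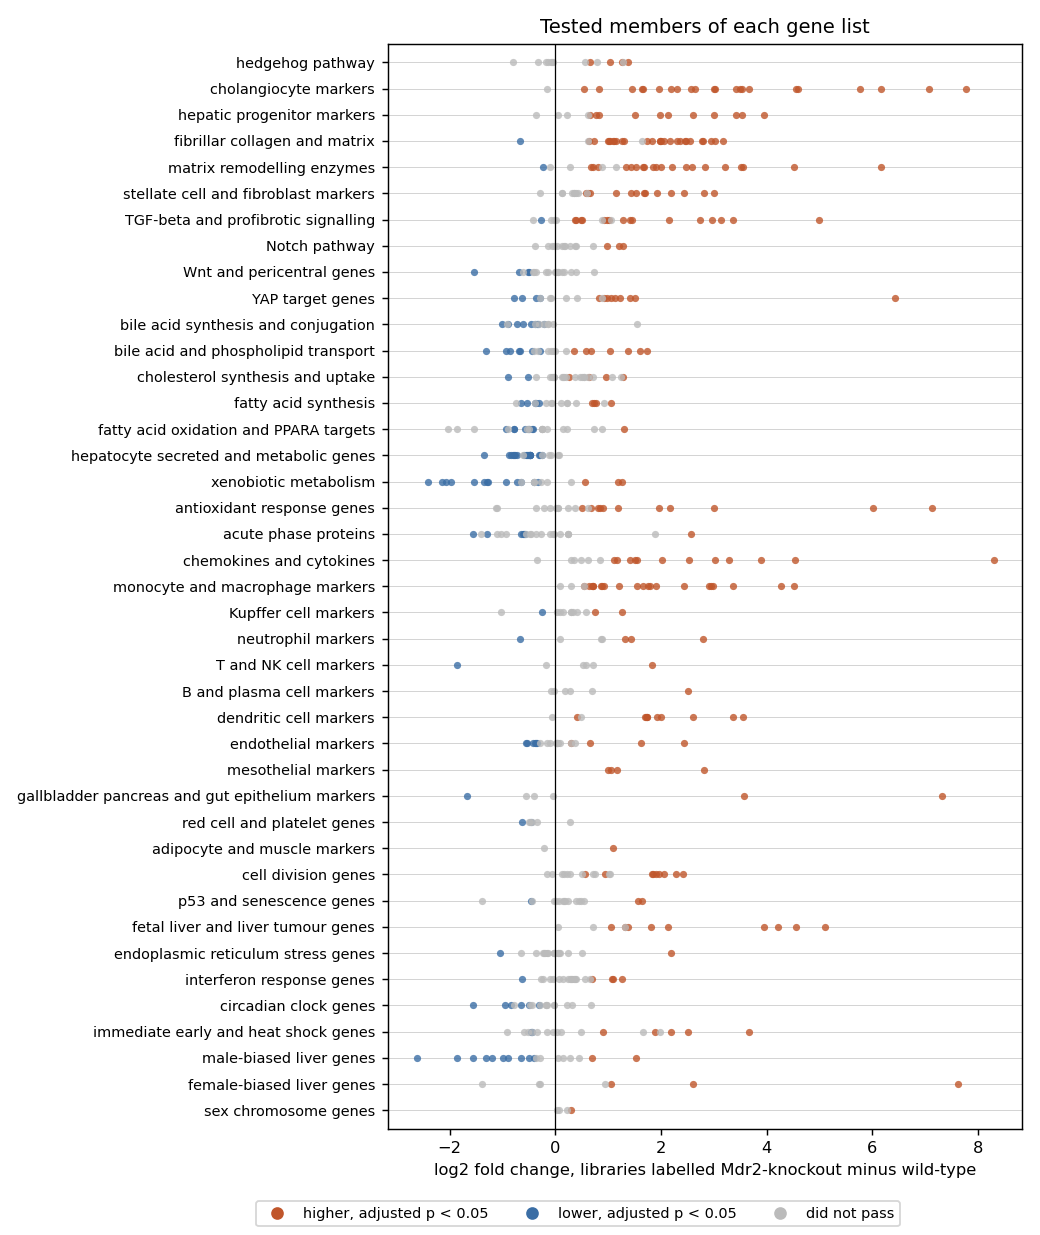
Each point is the fitted log2 fold change (horizontal axis, labelled Mdr2-knockout minus labelled wild-type, TMM scaling) of 1 tested member of the list named on the vertical axis; orange and blue points passed an edgeR adjusted p of 0.05 as higher and lower, and grey points did not. Of the cholangiocyte markers, 22 of 23 lie to the right of 0 as higher, while 20 of 26 hepatocyte genes lie to the left as lower (9 with total-count scaling); fitted values of genes with 0 counts in a group are not bounds.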

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

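Each alternative was chosen before the data were examined. The count of genes changed, Mdr2-knockout against wild-type, was 4685 and ran from 3541 to 6273 at the same threshold. That of genes changed at least 2-fold, Mdr2-knockout against wild-type, ran from 1098 to 2081 apart from the FPKM. The alternatives for this count include the test against a 1.5-fold change, whose calls carry no 2-fold cut. With total counts, genes higher were 5943, genes lower 330 and genes lower at least 2-fold 50. The FPKM, which carry the same scaling, gave 4794 higher and 308 lower with a pseudocount of 1, 4773 and 309 with 0.1 (43 lower at 2-fold), and 5932 and 300 without the minimum. They also differ in test, log scale and filter, and these causes were not separated. With a pseudocount of 1, which shrinks low genes, 2-fold changes fell to 517 (genes higher at least 2-fold 490, lower 27), and to 521 (491 and 30) without the minimum. An adjusted p under 0.01 left 2654 genes (1654 higher, 1000 lower). Of the 4685 calls, 63.3% were shared with total counts, 48% with the FPKM at a pseudocount of 1, 86.1% with DESeq2 and 96.5% with limma-voom, all in the same direction. Without 1 library, 72% to 86.3% were shared.

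The replicate number as a block gave 4568 genes, 4313 of them shared. Same-numbered libraries had deviations correlated at 0.0842, 0.0449 and -0.0759, and not every library correlated best with its own number. These values show no sign of pairing by number. Deviations from the mean of only 3 libraries cannot exclude a shared litter, day or batch, on which the labels are silent.

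Abcb4 kept its direction and call in the alternatives run for single genes (log2 fold change 0.45 to 0.87), and the cholangiocyte and progenitor lists in those run for lists (highest adjusted p 0.0278). The fibrillar collagen and matrix list lost its call with an estimated correlation (0.0949, with a range over alternatives of 1.55e-38 to 0.0949). The estimate was 0.424 against the preset of 0.01. Lists with estimates under the preset also lost their calls, such as mesothelial markers (-0.238, camera adjusted p = 0.122) and clock genes (-0.0441, 0.122). The size of the correlation therefore need not be the reason, which was not tested. The hedgehog pathway list passed with fry (0.0391; range 0.0391 to 0.891), a test that by construction sets no genes beside it. In the library overview the first principal component held 75.1% with a prior count of 0.5; the cause was not tested.

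Of 4402 values of 264 named genes other than Abcb4, 4073 kept their side of the threshold, 220 lost the call, 100 gained it and 9 turned. A turn was counted only where the main fit or the alternative passed. The 4073 can therefore hold uncalled values that changed sign. The gene Spop turned to 0.21 with total counts and with each FPKM setting, passing there, and gene Nr1h3 to 0.0409, 0.0411, 0.0421 and 0.0411, not passing. The gene Hba-a1, -0.43 with all libraries and not called, ran from -0.78 (without labelled wild-type replicate 2) to 0.60 (without labelled wild-type replicate 3, edgeR adjusted p = 0.00381). Its counts were 342, 326 and 1414 in labelled wild-type replicates 1, 2 and 3. Of 758 list values, counted in the same way, 707 kept their side of the threshold, 40 lost the call, 8 gained it and 3 turned. The gallbladder pancreas and gut epithelium markers list turned with the FPKM without the minimum (camera adjusted p = 0.00978). The female-biased liver genes list turned with the FPKM at a pseudocount of 1 (0.99) and without the minimum (0.117). The cause was not tested.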

Other observations

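The tests of an exchange of both groups and of a lower share of hepatocyte RNA were chosen after the values they use had been seen. A set of 35 called genes with a mean of at least 1 CPM in 1 group had no more than 3 counts over the other. Of these, 34 were read in the labelled Mdr2-knockout libraries and 1, Cyp2c69, in the labelled wild-type libraries. The genes named next were chosen after their values were seen. The trefoil factor gene Tff2 had 0 counts in the labelled wild-type and 91 in the labelled Mdr2-knockout group, the Wnt ligand genes Wnt7b and Wnt10a 2 against 112 and 0 against 68, and the diamine oxidase gene Aoc1 0 against 72. The gastric protease gene Ctse had 3 against 69, the podoplanin gene Pdpn, a marker of lymphatic endothelium, 1 against 74, and the doublecortin-like kinase gene Dclk1, a tuft cell marker, 1 against 81. The uncharacterised gene 2310057J18Rik had 1 against 1431, the most reads of the set.

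Abcb4, the gene named as knocked out, was higher in the libraries labelled Mdr2-knockout, and an allele that leaves most of the transcript in place was not tested. The choice among the 4 scalings is argued against, since the lowest log2 fold change over them was 0.56 (SE 0.12). Against TMM, log2 fold changes shifted by a median of -0.01 with RLE, 0.06 with upper-quartile and 0.29 with total-count scaling. All 4 are relative to the measured genes, so a larger shift common to all genes was not tested. Reads of Abcb1a and Abcb1b counted on Abcb4 stay open: the paralogs' summed count was at most 0.115 of the Abcb4 excess in any of those libraries, but the bound of 1 set beforehand for that ratio was wrong, since a read counted on Abcb4 is missing from the paralogs' counts. An exchange of both groups as a whole stays open too, since 3 of 3 labelled Mdr2-knockout libraries lay above each labelled wild-type library and the tables cannot be told apart from tables with the names exchanged. Against it stands only background on this model of bile duct injury and fibrosis: 22 of 23 cholangiocyte, 27 of 30 matrix, 11 of 15 progenitor and 21 of 24 monocyte and macrophage genes were higher in the labelled Mdr2-knockout libraries, as the labels would have it.

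Of the 2-fold changes, 93.7% were higher in the labelled Mdr2-knockout libraries. The choice among the 4 scalings is argued against by the lowest share over them, 93.3%, while a larger shift common to all genes was not tested. Gene length is argued against by a share of 86.9% after a smooth length trend was removed (1102 higher, 166 lower). Spearman's rho of log2 fold change and length across genes, which are not independent, was 0.149. A lower share of hepatocyte RNA, raising every other cell type alike, is argued against as the whole cause by the median log2 fold changes. The median was 3.00 for cholangiocyte markers (3.00 also with the 1 gene at 0 counts set to its bound). For endothelial markers it was 0.03, a difference of 2.97 (bootstrap 95% interval 2.09 to 3.70). The bootstrap resampled the genes of each list. These genes are not independent, and the interval does not measure the spread between libraries. More bile duct, matrix-forming, monocyte, macrophage and dendritic cells, or more of their transcripts per cell, may both contribute and bulk libraries do not separate them.

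For the 35 genes read in 1 group, a chromosome segment carried with the knockout allele is argued against: 0% lie within 20 Mb of Abcb4. Among all tested genes, 52.4% of the 21 within 5 Mb of Abcb4 were called against 37.2% elsewhere (odds ratio 1.85, 95% interval 0.714 to 4.87), and the Benjamini-Hochberg adjusted p of Fisher's exact test (two-sided) over windows of 5, 10 and 20 Mb was 0.265, 0.265 and 0.906. No other explanation of the set was tested.

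With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split called 4685 genes and the highest of the other splits 1, so 1 of 10 splits gave as many, and at 2-fold the values were 1499 and 1, again 1 of 10. The camera p, unadjusted, was 2.93e-44 for cholangiocyte markers against a smallest other of 1.4e-08, 1.91e-13 against 4.79e-05 for progenitor markers and 2.64e-28 against 6e-15 for matrix genes, 1 of 10 splits in each. For the hedgehog list it was 0.685, and 4 of 10 splits gave a p as small, the smallest other being 0.138. Each other split sets 2 libraries of a label and 1 of the other against the reverse, so part of the labelled difference stays in it, and its small p-values do not measure chance alone.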
